A study of Drosophila melanogaster with 72 samples.

How the data were processed

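RNA-seq was read from 72 libraries of Drosophila melanogaster, 36 groups of 2 libraries each, in 6 experiments. Embryos were collected in windows of 0 to 0.5, 1 to 1.5 and 2.5 to 3 h, and larvae at 24, 48 and 72 h after egg laying. Per the labels, the experiments compared wild type with larvae labelled zygotic mutant, whose gene the sample labels do not name, with embryos in which IntS11 or IntS9 was mislocalized, and with an IntS11 knockdown, and control embryos with embryos given alpha-amanitin. A rescue experiment compared wild type, mislocalized IntS11, and Flag-tagged IntS11 WT or E203Q. Per the labels, total RNA was depleted of ribosomal RNA and made into strand-specific libraries. Whether the counting used the strand is not given in the sources used here.

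The authors' notes name Trimmomatic 0.39, STAR 2.7.10a, RSEM 1.3.1, DESeq2 1.40.2 and build dm6. The deposited expected counts are RSEM estimates of reads per gene, not normalized, and were the values analysed. The deposited TPM values were scaled by the authors for transcript length and depth. They served only in the rule for naming genes, for its minimum and for the separation of the libraries. The deposited FPKM values, which the authors scaled by length and depth, were not used. Each file held 16680 genes, of which 16448 were matched to a current symbol in the reference annotation. Expected counts summed to between 2061575 and 26074431 per library. In the knockdown experiment wild type libraries held at most 2590455 and knockdown libraries at least 10415095. Many near-identical copies, such as histone genes, had 0 counts in all libraries and others equal counts, and how shared reads were treated is not given in the sources used here, so values of such copies are uncertain. Floors and intervals cover counting error only.

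Expected counts were rounded and fitted with edgeR 4.0.16 in R 4.3.3, 1 fit per experiment with 1 mean per group, TMM scaling, filterByExpr and the robust quasi-likelihood test. Adjusted p-values follow Benjamini and Hochberg, with a threshold of 0.05, and SE is the absolute log2 change over the square root of F. Levels are CPM, counts scaled by the TMM-adjusted library size, as the mean of the libraries of a group. For 42 gene lists, members called were counted with adjustment over all genes and over the list alone, and limma 3.58.1 camera compared each list with all other genes at a preset correlation of 0.01. Where an arm had 0 counts, the fold of a gene is a lower bound against 3 counts over the group, and medians at bound treat genes with 3 or fewer counts in an arm in the same way. Differences between the effects in different experiments were tested as interaction terms in a joint fit. Genes lowered at least 2-fold by alpha-amanitin, or by IntS11 mislocalization, were read as lists in experiments that share no library with them, and shared calls were tested with a one-sided Fisher's exact test.

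The comparisons, tests, gene lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule took IntS11 and IntS9, the 8 largest rises and 8 largest falls among called genes, and up to 4 members of each list. Rises and falls needed both libraries beyond the other arm in TPM and a mean TPM of at least 5 in an arm. Left out of these were unnamed genes and noncoding genes with prefixes such as snoRNA, while snRNAs and other noncoding transcripts could pass. The rule allowed more genes than the text holds, and the genes and lists given were picked from those allowed after the values were seen. Alternatives were RLE size factors, total counts, no filter, DESeq2 1.42.0, only the groups compared, a replicate block, leaving out each library, an estimated correlation and stricter lists. The procedure was tested on simulated data with 200 changed genes. With the spread of the IntS11 mislocalization libraries at 2.5 to 3 h, 88.1%, 98.5% and 100% of genes changed by 1.5, 2 and 4-fold were recovered, and 3.05% of calls were false. With that of the knockdown, 59.7%, 88.1% and 100% were recovered, and 6.78% of calls were false. The simulations changed few of the 8233 and 8796 genes fitted, with rises and falls in equal number. In the real comparisons they stand for, most genes were called, so these rates may not hold there. With 2 libraries per group, other splits of the samples were not counted.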

Results

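Transcripts of IntS11, the endonuclease subunit of the Integrator complex (dm6, chromosome 3R, 29745337 to 29747513), fell in each knockdown window, with log2 changes of -3.84 ± 0.15, -4.07 ± 0.15 and -2.77 ± 0.13 (SE, n = 2 libraries per group) at 0 to 0.5, 1 to 1.5 and 2.5 to 3 h. In zygotic mutant larvae the changes were -1.63 ± 0.11, -1.37 ± 0.15 and -2.15 ± 0.12 at 24, 48 and 72 h after egg laying. The IntS11 mislocalization line held slightly less IntS11 RNA than wild type, at -0.39 ± 0.08, -0.53 ± 0.08 and -0.73 ± 0.08, while in the rescue experiment the same comparison gave -0.01 ± 0.06 and -0.02 ± 0.06, neither called. Both Flag lines carried far more: at 1 to 1.5 h IntS11 stood at 126 ± 4.68 CPM (SD, n = 2) in wild type, 126 ± 0.778 in the mislocalized line, 2128 ± 112 with Flag IntS11 WT and 2019 ± 104 with Flag IntS11 E203Q. The Flag lines did not differ from each other in IntS11 RNA (0.08 ± 0.05 and -0.08 ± 0.05, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.241 and 0.177). IntS9 (3L, 16103432 to 16105627) rose a little in its own mislocalization line, by 0.18 ± 0.07, 0.38 ± 0.07 and 0.28 ± 0.07. Adjusted p-values measure the spread between these samples alone, since the labels do not say whether replicates were separate collections.

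Alpha-amanitin, which blocks RNA polymerase II, lowered early patterning transcripts at 1 to 1.5 h (n = 2 libraries per group). Against 0 counts in the treated embryos, dan fell at least 384-fold from 31.3 CPM, Ama at least 219-fold and SNCF at least 73.6-fold. Dorsoventral genes Ance, sog and twi also reached 0 counts and fell at least 93.9, 71.9 and 55.6-fold. Few genes rose by much: Eip75B went from 14.4 to 38.97 CPM (1.44 ± 0.08) and NAT1 from 593 to 1091 CPM (0.88 ± 0.08). Early zygotic genes of the minor wave fell in 37 of 39 cases, 38 adjusted over the list alone, while 1 rose, with a median of -5.84 or -4.97 at bound (camera adjusted p = 8.47e-27, but adjusted p = 0.0898 with an estimated correlation). Here and below, "at bound" sets each gene with 3 or fewer counts in one arm to the smallest fold that 3 counts over the group allow. Of the 39 minor wave genes 28 were at bound here, and the sum of the list went from 617 to 457 CPM. Dorsoventral patterning genes fell in 23 of 23 cases, 23 adjusted over the list alone, with a median of -7.37 or -4.81 at bound (camera adjusted p = 4.5e-21, but adjusted p = 0.079 with an estimated correlation). Camera calls held with an estimated correlation between genes too, except where that p is given. Of 8517 genes tested, 1328 were called higher and 1523 lower, 2851 in all, of which 21 and 568 by at least 2-fold. The 46.6% of calls that were higher became 52.8% with RLE size factors and 38.3% with total counts. The genes named had adjusted p up to 2.58e-06 (edgeR, Benjamini-Hochberg).

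By 2.5 to 3 h, treated embryos (n = 2 libraries per group) held far less zygotic RNA and more maternal RNA than controls. The transcription factors opa and salm and the segment polarity gene nkd, at 371, 212 and 216 CPM in controls, had 0 counts. These were falls of at least 4730, 2700 and 2750-fold. The gap gene Kr went from 336 to 0.418 CPM (-9.62 ± 0.11), and Sry-alpha from 1928 to 7.94 CPM (-7.92 ± 0.12). Of maternal transcripts, mtrm, osk, gnu and png stood 6.35 ± 0.09, 5.49 ± 0.07, 5.28 ± 0.09 and 4.48 ± 0.10 log2 units above controls, with osk at 1312 CPM. Other transcripts above controls were dhd (7.77 ± 0.11), fs(1)Ya (7.25 ± 0.10), Tpi (7.09 ± 0.11) and Hsp26 (5.52 ± 0.07). Early zygotic genes fell in 39 of 39 cases, 39 adjusted over the list alone, with a median of -8.99 or -8.95 at bound (camera adjusted p = 4.38e-13, but adjusted p = 0.215 with an estimated correlation). Maternal transcripts cleared at the transition rose in 12 of 13 cases, 12 adjusted over the list alone, while 1 fell, with a median of 2.89 (camera adjusted p = 3.77e-05, but adjusted p = 0.289 with an estimated correlation). The comparison called 7638 of 8517 genes, 3403 higher and 4235 lower, and by at least 2-fold 2237 and 2412. For the genes named, adjusted p reached 3.52e-09 (edgeR, Benjamini-Hochberg).

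Embryos with mislocalized IntS11 already differed from wild type at 0 to 0.5 h (n = 2 libraries per group). Atg18b went from 13.98 to 313 CPM, Hsp23 from 18.4 to 409.9 CPM, Ect3 from 3.41 to 132 CPM and mfas from 5.82 to 64.1 CPM. Their log2 changes were 4.48 ± 0.10, 4.48 ± 0.10, 5.27 ± 0.15 and 3.46 ± 0.11, and the apoptosis gene skl rose by 4.28 ± 0.40. Falls were seen in alph (109 to 4.82 CPM, -4.48 ± 0.12), link (-3.995 ± 0.14) and Ptr (-3.66 ± 0.12). The patterning genes twi, ftz, opa, run, wg and nkd changed by -3.55 ± 0.24, -3.27 ± 0.18, -3.66 ± 0.24, -2.70 ± 0.24, -3.39 ± 0.27 and -3.60 ± 0.29. Wild type libraries of this window held these patterning transcripts at low levels, ftz at 11.7 and opa at 15.9 CPM. At 1 to 1.5 h wild type of this experiment held ftz at 36.3 and opa at 17.9 CPM. Hox transcripts abd-A, Scr and Ubx had 63, 34 and 40 counts in wild type at 0 to 0.5 h. Under alpha-amanitin at 1 to 1.5 h Scr and Ubx had 0 counts, against 25 each in controls. Older embryos in the wild type collections would bring such zygotic RNA. The falls in patterning genes cannot be told apart from them. Heat shock genes rose in 11 of 16 cases, 11 adjusted over the list alone, with a median of 1.90 or 1.79 at bound (camera adjusted p = 6.6e-09, but adjusted p = 0.067 with an estimated correlation). Minor wave genes fell in 28 of 39 cases, 31 adjusted over the list alone, with a median of -1.46 (camera adjusted p = 1.95e-16). Segment polarity genes fell in 9 of 9 cases, 9 adjusted over the list alone, with a median of -3.12 or -2.97 at bound (camera adjusted p = 4.58e-09). Calls numbered 2790 of 8804 genes, with 1483 higher and 1307 lower, 566 and 514 of them by at least 2-fold, and 53.2% higher became 43.5% with RLE size factors and 48.6% with total counts. The largest adjusted p of the genes named was 0.000699 (edgeR, Benjamini-Hochberg).

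The minor wave of zygotic transcription was lower throughout the IntS11 line at 1 to 1.5 h (n = 2 libraries per group). The zinc finger gene term went from 312 to 10.4 CPM, bnk from 243 to 12.9 CPM, halo from 175 to 7.86 CPM, Sry-alpha from 387 to 22.7 CPM and Z600 from 64.1 to 1.22 CPM. Their log2 changes were -4.90 ± 0.13, -4.24 ± 0.10, -4.47 ± 0.11, -4.09 ± 0.11 and -5.73 ± 0.17. Those of SNCF, link, Ptr and D were -5.66 ± 0.15, -5.91 ± 0.14, -5.70 ± 0.13 and -5.25 ± 0.18, and those of kni, gt, tll and ftz were -4.67 ± 0.18, -3.57 ± 0.14, -3.76 ± 0.17 and -4.37 ± 0.14. Rises included those of Ect3, Hsp23, Atg18b, GLaz and tyn (4.27 ± 0.14, 3.82 ± 0.10, 3.69 ± 0.10, 3.90 ± 0.26 and 3.70 ± 0.16). Maternal osk was 0.73 ± 0.09 above wild type. The early zygotic genes fell in 39 of 39 cases, 39 adjusted over the list alone, with a median of -3.28 (camera adjusted p = 6.44e-46). Cellularization genes fell in 6 of 6 cases, 6 adjusted over the list alone, with a median of -4.17 (camera adjusted p = 1.89e-14). Gap genes fell in 9 of 10 cases, 9 adjusted over the list alone, with a median of -3.30 (camera adjusted p = 6.96e-11, but adjusted p = 0.0509 with an estimated correlation). Among 8804 genes, 1998 were called higher and 2164 lower (4162 together), including 579 and 746 changed at least 2-fold, and 48% higher became 51.7% with RLE size factors and 55.1% with total counts. Each gene named had an adjusted p of 5.75e-06 or less (edgeR, Benjamini-Hochberg).

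By 2.5 to 3 h, IntS11-mislocalized embryos (n = 2 libraries per group) held less of most patterning transcripts and more maternal RNA. The segmentation gene ftz went from 310.4 to 5.34 CPM, opa from 393 to 6.29 CPM, ptc from 833 to 37.9 CPM, twi from 259 to 6.90 CPM and Kr from 180.4 to 10.5 CPM. Log2 changes were -5.86 ± 0.11, -5.96 ± 0.15, -4.46 ± 0.11, -5.23 ± 0.13 and -4.10 ± 0.14 for these genes. The cellularization gene slam went from 3066 to 529.9 CPM, and nkd, en, run, kni, pnr and vnd changed by -4.36 ± 0.15, -4.51 ± 0.16, -4.54 ± 0.14, -4.82 ± 0.14, -5.66 ± 0.20 and -5.56 ± 0.21. Cuticle genes TwdlM and Cpr65Ea and the muscle gene Mlp60A had 0 counts in the mutant, falls of at least 436, 320 and 142-fold. Whether older embryos in the wild type collections held these transcripts was not tested. Maternal osk rose from 39.1 to 639 CPM, smg from 233 to 2047 CPM and bcd from 23.9 to 262 CPM (4.03 ± 0.10, 3.14 ± 0.12 and 3.45 ± 0.10). Jabba, CAH2, rost and Hsp22 rose by 5.89 ± 0.10, 5.68 ± 0.11, 4.36 ± 0.13 and 3.83 ± 0.10. Genes of the minor wave fell in 35 of 39 cases, 35 adjusted over the list alone, while 3 rose, with a median of -3.67 (camera adjusted p = 1.99e-12). Dorsoventral genes fell in 23 of 23 cases, 23 adjusted over the list alone, with a median of -4.14 (camera adjusted p = 1e-10). The maternal transcripts cleared at the transition rose in 13 of 13 cases, 13 adjusted over the list alone, with a median of 2.23 (camera adjusted p = 1.11e-08). Of 8804 genes tested, 2651 were called higher and 4680 lower, 7331 in all, of which 1397 and 2880 by at least 2-fold. The genes named had adjusted p up to 5.08e-10 (edgeR, Benjamini-Hochberg). Scaling by total counts moved the median of all genes by 0.36 log2 units and the share of calls that were higher from 36.2% to 49.4%.

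Mislocalized IntS9, another Integrator subunit, gave more calls than mislocalized IntS11 at 0 to 0.5 h (n = 2 libraries per group). Transcripts of Tbh, slbo and Spn43Aa, at 40.1, 25.4 and 21.2 CPM in the mutant, had 0 counts in wild type. These were rises of at least 457, 290 and 242-fold. Hsp23 went from 48.9 to 875 CPM and Hsp68 from 11.7 to 163 CPM, and skl rose by 6.79 ± 0.23. In the other direction, term, spo, ftz and bnk had 0 counts in the mutant, falls of at least 590, 270, 254 and 183-fold, term from 46.6 CPM. The segment polarity genes ptc and nkd went from 58.8 to 0.156 CPM and 23.5 to 0.291 CPM, and run and kni changed by -6.83 ± 0.27 and -5.52 ± 0.27. Heat shock genes rose in 12 of 17 cases, 12 adjusted over the list alone, while 1 fell, with a median of 1.49 (camera adjusted p = 6.52e-08). Early zygotic genes fell in 33 of 39 cases, 34 adjusted over the list alone, which also had 2 rises, with a median of -4.88 or -4.47 at bound (camera adjusted p = 1.69e-30). In wild type their sum was already 1043 CPM in this window, against 1397 at 1 to 1.5 h. The falls thus depend on zygotic RNA in the wild type collections. Older embryos in these collections would bring such RNA, and their share was not tested. An effect of the line in this window cannot be told apart from them. Pair-rule genes fell in 8 of 10 cases, 9 adjusted over the list alone, while 1 rose, with a median of -6.22 or -6.02 at bound (camera adjusted p = 2.53e-13). The comparison called 4844 of 9217 genes, 2401 higher and 2443 lower, and by at least 2-fold 1188 and 678. The 49.6% higher became 54.8% with total counts and 40.2% with RLE size factors. For the genes named, adjusted p reached 3.97e-13 (edgeR, Benjamini-Hochberg).

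In the IntS9 line at 1 to 1.5 h (n = 2 libraries per group), term, D, Bsg25A, spo and twi had 0 counts, against 54.4 CPM for term in wild type. These were falls of at least 711, 622, 573, 321 and 259-fold, in that order. The genes bnk, ptc, halo, opa, run, sisA and Z600 changed by -8.72 ± 0.19, -8.20 ± 0.14, -7.42 ± 0.17, -6.74 ± 0.23, -5.80 ± 0.22, -5.53 ± 0.29 and -5.25 ± 0.23. The minor spliceosome RNA snRNA:U11 changed by -2.79 ± 0.22. Hsp23, Hsp68, ImpL3 and skl rose by 4.15 ± 0.07, 3.64 ± 0.07, 3.85 ± 0.15 and 4.67 ± 0.17. Mdr65, Swim, Phk-3 and Obp56d had 0 counts in wild type and rose at least 377, 169, 109 and 104-fold. Minor wave genes fell in 37 of 39 cases, 37 adjusted over the list alone, and their sum went from 1397 to 434 CPM. Their median log2 change was -5.53 or -5.47 at bound (camera adjusted p = 1.65e-46). Cellularization genes fell in 6 of 6 cases, 6 adjusted over the list alone, with a median of -6.34 or -6.18 at bound (camera adjusted p = 2.11e-16). Segment polarity genes fell in 9 of 9 cases, 9 adjusted over the list alone, with a median of -7.06 or -6.52 at bound (camera adjusted p = 1.43e-16). Cuticle protein markers rose in 41 of 46 cases, 42 adjusted over the list alone, while 1 fell, with a median of 6.21 or 3.08 at bound (camera adjusted p = 5.31e-06). Summed without the reductase gene Cpr, which the prefix of this list took in, the cuticle members went from 3.61 to 94.8 CPM. Calls numbered 5479 of 9217 genes, with 2882 higher and 2597 lower, 1242 and 931 of them by at least 2-fold. The 52.6% higher became 47.3% with RLE size factors and 56.3% with total counts. The largest adjusted p of the genes named was 3.01e-05 (edgeR, Benjamini-Hochberg).

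Zygotic transcripts such as term and twi were not detected in the IntS9 line at 2.5 to 3 h (n = 2 libraries per group). From 752, 445, 310.2, 258 and 231 CPM in wild type, term, SNCF, bnk, ftz and twi reached 0 counts. They were at least 7620, 4510, 3150, 2620 and 2340-fold lower. Maternal osk, gnu, png and bcd rose by 3.999 ± 0.07, 3.43 ± 0.14, 1.89 ± 0.13 and 4.17 ± 0.08, and Hsp23 by 3.96 ± 0.07. Tig rose from 0.807 to 249 CPM (8.25 ± 0.11), and Tbh and Cpr49Ae, at 0 counts in wild type, rose at least 384 and 249-fold. The early zygotic genes fell in 39 of 39 cases, 39 adjusted over the list alone, and their sum went from 11790 to 403 CPM. The median of this group was -9.67 or -8.80 at bound (camera adjusted p = 1.04e-42). Gap genes fell in 10 of 10 cases, 10 adjusted over the list alone, with a median of -9.71 or -8.70 at bound (camera adjusted p = 1.93e-11), and their sum went from 1298 to 149 CPM. Dorsoventral genes fell in 23 of 23 cases, 23 adjusted over the list alone, with a median of -8.76 or -8.54 at bound (camera adjusted p = 7.01e-23). Among maternal RNAs, those cleared at the transition rose in 13 of 13 cases, 13 adjusted over the list alone, with a median of 2.50 (camera adjusted p = 5.58e-10). Among 9217 genes, 3724 were called higher and 3966 lower (7690 together), including 2101 and 2509 changed at least 2-fold. The 48.4% higher became 53.3% with total counts and 42.8% with RLE size factors. Each gene named had an adjusted p of 1.19e-11 or less (edgeR, Benjamini-Hochberg).

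Genes that alpha-amanitin lowered at least 2-fold were read as a group in the other experiments, which share no library with it. At 1 to 1.5 h these genes were lower in the IntS11 line, where 392 of 563 fell and 37 rose, with a median log2 change of -2.16 or -2.10 at bound (camera adjusted p = 2.5e-41). In the IntS9 line 448 of 562 of them fell and 46 rose, median -3.99 or -3.73 at bound (camera adjusted p = 9.87e-73). In the knockdown 269 of 550 fell and 94 rose, median -1.10 or -0.88 at bound (camera adjusted p = 0.000844, but adjusted p = 0.0983 with an estimated correlation). At 2.5 to 3 h the amanitin-lowered genes had medians of -1.99 in the IntS11 line, -2.29 or -2.26 at bound in the IntS9 line and -1.39 in the knockdown, with 1784 of 2191, 1731 of 2288 and 1361 of 2118 genes lower. The camera adjusted p-values were 2.77e-18, 7.56e-21 and 7.56e-21, or 0.000169, 0.000153 and 0.000844 with an estimated correlation.

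In every window of the knockdown experiment, knockdown libraries were deeper than wild type ones and held more 7SL RNA, at least 15.7% against at most 7.02% of counts. A difference in library preparation therefore cannot be separated from the knockdown in its comparisons. In knockdown embryos at 0 to 0.5 h (n = 2 libraries per group), Ect3 rose from 1.75 to 1014 CPM (9.15 ± 0.24). The genes Osi6, Osi7, link, sala, bnk and ptc changed by -7.14 ± 0.28, -5.69 ± 0.28, -5.41 ± 0.31, -5.24 ± 0.42, -4.14 ± 0.33 and -1.69 ± 0.25. These falls depend on their RNA in wild type, where the presence of older embryos was not tested. Hsp23, Hsp68 and ImpL3 rose by 6.15 ± 0.14, 4.23 ± 0.20 and 3.69 ± 0.29. Maternal wisp, stg and cup changed by -2.13 ± 0.16, -1.69 ± 0.18 and -1.53 ± 0.12 and png by 1.71 ± 0.13. The larval serum and fat body transcripts Lsp2, Fbp1 and Tsf1, at 401, 167 and 56.9 CPM, had 0 counts in wild type. They were at least 757, 315 and 107-fold higher. Fat body markers rose in 7 of 7 cases, 7 adjusted over the list alone, and their sum went from 49.8 to 890 CPM. As a group they had a median of 9.98 or 6.37 at bound (camera adjusted p = 8.64e-07, but adjusted p = 0.401 with an estimated correlation). Muscle markers fell in 7 of 12 cases, 7 adjusted over the list alone, while 2 rose, and summed from 646 to 255 CPM, with a median of -1.36 (camera adjusted p = 0.0177, but adjusted p = 0.37 with an estimated correlation). Genes of the minor wave fell in 25 of 39 cases, 24 adjusted over the list alone, while 1 rose, with a median of -2.20 or -1.97 at bound (camera adjusted p = 0.00107, but adjusted p = 0.37 with an estimated correlation). Of 9681 genes tested, 3822 were called higher and 2868 lower, 6690 in all, of which 2517 and 1597 by at least 2-fold. The genes named had adjusted p up to 7.43e-06 (edgeR, Benjamini-Hochberg). Total counts as the scale moved the median of all genes by -0.62 and the share of calls that were higher from 57.1% to 35.3%.

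The knockdown at 1 to 1.5 h (n = 2 libraries per group) held less RNA of the zygotic genes nkd, run, spo, Kr, opa and Brd, which changed by -3.999 ± 0.42, -3.27 ± 0.27, -3.23 ± 0.37, -3.09 ± 0.27, -3.003 ± 0.24 and -4.08 ± 0.55. Hsp23 and Hsp68 rose by 6.80 ± 0.14 and 5.42 ± 0.22. Cuticle genes Lcp4 and Lcp65Ab1, the digestive enzyme gene Jon65Aiv and Lsp2 had 0 counts in wild type. They were at least 214, 139, 77.5 and 109-fold higher, in that order. TwdlF, with 0 counts in the knockdown, was at least 59.8-fold lower than in wild type, where the presence of older embryos was not tested. Early zygotic genes fell in 35 of 39 cases, 35 adjusted over the list alone, while 1 rose, with a median of -2.04 (camera adjusted p = 8.66e-07, but adjusted p = 0.0886 with an estimated correlation). Gap genes fell in 10 of 10 cases, 10 adjusted over the list alone, with a median of -2.55 (camera adjusted p = 0.00394, but adjusted p = 0.193 with an estimated correlation). Maternal transcripts cleared at the transition fell in 10 of 13 cases, 10 adjusted over the list alone, while 3 rose, with a median of -0.91 (camera adjusted p = 0.00417, but adjusted p = 0.193 with an estimated correlation). Digestive enzymes of the gut rose in 25 of 25 cases, 25 adjusted over the list alone, and their sum went from 45.6 to 434 CPM. Over this list the median was 8.15 or 4.33 at bound (camera adjusted p = 1.26e-07, but adjusted p = 0.193 with an estimated correlation). The comparison called 7041 of 9681 genes, 4040 higher and 3001 lower, and by at least 2-fold 2611 and 1739. For the genes named, adjusted p reached 2.16e-05 (edgeR, Benjamini-Hochberg). The share higher was 57.4%, and 41.5% when scaled by total counts, which moved the median of all genes by -0.44.

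In the 2.5 to 3 h knockdown (n = 2 libraries per group), bnk, halo, Z600, tll, kni, Kr and zen changed by -5.70 ± 0.13, -5.47 ± 0.16, -5.06 ± 0.14, -4.48 ± 0.21, -4.33 ± 0.18, -4.53 ± 0.15 and -4.86 ± 0.19. Maternal gnu, osk and png rose by 4.60 ± 0.16, 3.14 ± 0.11 and 2.74 ± 0.24, and Hsp23 and Hsp26 by 5.51 ± 0.12 and 4.31 ± 0.13. TwdlB, Osi19 and Ccp84Ae reached 0 counts, at least 532, 198 and 127-fold lower. These falls depend on their RNA in the wild type collections, where the presence of older embryos was not tested. Lsp1beta, Fbp2 and Dpt, with 0 counts in wild type, were at least 248, 129 and 38.5-fold higher. Minor wave genes fell in 39 of 39 cases, 39 adjusted over the list alone, and their sum went from 10220 to 859 CPM. Their median log2 change was -3.48 (camera adjusted p = 7.53e-35). Cellularization genes fell in 6 of 6 cases, 6 adjusted over the list alone, with a median of -4.53 (camera adjusted p = 5.64e-16). Gap genes fell in 10 of 10 cases, 10 adjusted over the list alone, with a median of -4.15 (camera adjusted p = 2.64e-13). The maternal transcripts cleared at the transition rose in 12 of 13 cases, 12 adjusted over the list alone, while 1 fell, with a median of 1.25 (camera adjusted p = 2.7e-05). Muscle markers fell in 12 of 12 cases, 12 adjusted over the list alone, and their sum went from 5076 to 507 CPM. The median of this group was -3.43 (camera adjusted p = 1.42e-19). Calls numbered 7331 of 9681 genes, with 3844 higher and 3487 lower, 2332 and 2393 of them by at least 2-fold. The largest adjusted p of the genes named was 5.97e-06 (edgeR, Benjamini-Hochberg). Total counts moved the median of all genes by -0.35 and RLE size factors by -0.30. The share of calls that were higher went from 52.4% to 40% and 41.7%.

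The rescue experiment repeated the IntS11 mislocalization with other libraries. At 1 to 1.5 h (n = 2 libraries per group) LanA went from 12.4 to 794 CPM, Hsp23 from 27.8 to 467 CPM, mgl from 11.5 to 209.6 CPM and Ect3 from 2.24 to 107 CPM. The log2 changes of these genes were 6.003 ± 0.06, 4.06 ± 0.07, 4.19 ± 0.07 and 5.58 ± 0.11. The zygotic genes twi, ftz, gt, kni, opa, bnk and halo changed by -4.17 ± 0.16, -3.87 ± 0.15, -4.44 ± 0.13, -3.77 ± 0.14, -3.76 ± 0.14, -3.83 ± 0.08 and -4.11 ± 0.10, and Ilp4, at 6.95 CPM in wild type, by -5.17 ± 0.27. The early zygotic genes fell in 39 of 39 cases, 39 adjusted over the list alone, with a median of -2.96 (camera adjusted p = 3.44e-88). Among 9156 genes, 3175 were called higher and 1714 lower (4889 together), including 675 and 574 changed at least 2-fold. Each gene named had an adjusted p of 1.02e-13 or less (edgeR, Benjamini-Hochberg). The share of calls that were higher was 64.9%, or 47.7% with RLE size factors and 49.4% with total counts.

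At 2.5 to 3 h (n = 2 libraries per group), bithorax region transcripts bxd and iab-4 were lower in the mislocalized line of the rescue experiment, bxd at least 337-fold. Transcripts of iab-4, Doc2 and knrl changed by -6.55 ± 0.18, -7.73 ± 0.19 and -6.40 ± 0.20. Eggshell genes of follicle cells, Cp36, Cp38 and Vm26Aa, were at least 81.1, 81.9 and 57.4-fold higher. Eggshell markers rose in 15 of 15 cases, 15 adjusted over the list alone, and their sum went from 1.88 to 83.96 CPM. As a group they had a median of 7.50 or 5.15 at bound (camera adjusted p = 0.00257). Genes of the minor wave fell in 34 of 39 cases, 34 adjusted over the list alone, while 3 rose, and their sum went from 15310 to 1980 CPM. Over this list the median was -2.96 (camera adjusted p = 2.53e-37). Among maternal RNAs, those cleared at the transition rose in 13 of 13 cases, 13 adjusted over the list alone, with a median of 1.95 (camera adjusted p = 1.19e-09). Of 9156 genes tested, 3738 were called higher and 3759 lower, 7497 in all, of which 1890 and 2260 by at least 2-fold. The 49.9% higher became 51.4% with total counts and 42.9% with RLE size factors. The genes named had adjusted p up to 1.88e-10 (edgeR, Benjamini-Hochberg).

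Flag IntS11 WT, compared with the mislocalized line at 1 to 1.5 h (n = 2 libraries per group), had more minor wave RNA and less of the transcripts that were high in that line. Ptr went from 3.49 to 90.5 CPM, SNCF from 1.61 to 41.2 CPM and Z600 from 0.963 to 21.2 CPM, log2 changes of 4.70 ± 0.08, 4.68 ± 0.13 and 4.46 ± 0.17. LanA went from 794 to 30.1 CPM, Atg18b from 198 to 20.2 CPM, Hsp23 from 467 to 87.6 CPM and mgl from 209.6 to 31.2 CPM. Ect3 and mfas changed by -5.24 ± 0.10 and -3.54 ± 0.09. Early zygotic genes rose in 39 of 39 cases, 39 adjusted over the list alone, and their sum went from 604 to 1686 CPM. Their median log2 change was 2.58 (camera adjusted p = 5.12e-99). Dorsoventral genes rose in 21 of 23 cases, 21 adjusted over the list alone, while 1 fell, with a median of 2.65 (camera adjusted p = 1.55e-31). The comparison called 2213 of 9156 genes, 933 higher and 1280 lower, and by at least 2-fold 550 and 349. For the genes named, adjusted p reached 2.92e-16 (edgeR, Benjamini-Hochberg). The share of calls that were higher was 42.2%, or 67.1% with RLE size factors.

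With Flag IntS11 WT at 2.5 to 3 h (n = 2 libraries per group), opa, lov, Doc2 and ths rose by 5.97 ± 0.09, 5.87 ± 0.09, 8.22 ± 0.18 and 5.86 ± 0.20 over the mislocalized line. Of these, opa went from 4.71 to 297 CPM, and bxd rose at least 217-fold. CAH2, Tig and Tsp74F changed by -5.07 ± 0.07, -5.76 ± 0.17 and -4.61 ± 0.15. Minor wave genes rose in 35 of 39 cases, 35 adjusted over the list alone, while 2 fell, and their sum went from 1980 to 15770 CPM. The median of this group was 3.14 (camera adjusted p = 6.95e-40). Maternal transcripts cleared at the transition fell in 13 of 13 cases, 13 adjusted over the list alone, with a median of -1.76 (camera adjusted p = 1.82e-09). Calls numbered 7175 of 9156 genes, with 3577 higher and 3598 lower, 1934 and 1849 of them by at least 2-fold. The 49.9% higher became 53.1% with RLE size factors and 43.9% with total counts. The largest adjusted p of the genes named was 1.34e-17 (edgeR, Benjamini-Hochberg).

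Flag IntS11 E203Q, with 1 residue of the protein changed, also had more minor wave RNA than the mislocalized line at 1 to 1.5 h (n = 2 libraries per group). SNCF went from 1.61 to 37.3 CPM, spo from 2.95 to 50 CPM, bnk from 6.36 to 99.9 CPM and Sry-alpha from 16.2 to 205 CPM. Log2 changes of these genes were 4.53 ± 0.13, 4.08 ± 0.11, 3.97 ± 0.08 and 3.66 ± 0.07. Apoptosis genes rpr, skl and W rose by 2.73 ± 0.28, 2.07 ± 0.15 and 1.42 ± 0.15. Falls were small, as in phr6-4, GM130 and Orc1 (-1.11 ± 0.07, -1.05 ± 0.07 and -0.70 ± 0.05). The early zygotic genes rose in 38 of 39 cases, 38 adjusted over the list alone, with a median of 2.50 (camera adjusted p = 7.66e-111). Genes of p53 and apoptosis rose in 7 of 8 cases, 7 adjusted over the list alone, with a median of 1.38 (camera adjusted p = 1.04e-06). Among 9156 genes, 1577 were called higher and 2423 lower (4000 together), including 1134 and 10 changed at least 2-fold. Each gene named had an adjusted p of 8.47e-08 or less (edgeR, Benjamini-Hochberg). The share higher was 39.4%, or 49.8% with RLE size factors and 67.8% with total counts.

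With Flag IntS11 E203Q at 2.5 to 3 h (n = 2 libraries per group) the zygotic genes rose less. Transcripts of salm went from 8.56 to 56.2 CPM, dan from 10.1 to 59.5 CPM and opa from 4.71 to 29.8 CPM (2.72 ± 0.08, 2.55 ± 0.10 and 2.66 ± 0.11). Genes of the minor wave rose in 39 of 39 cases, 39 adjusted over the list alone, and their sum went from 1980 to 5417 CPM. As a group they had a median of 1.53 (camera adjusted p = 2.57e-61). The maternal transcripts cleared at the transition fell in 10 of 13 cases, 11 adjusted over the list alone, with a median of -0.36 (camera adjusted p = 0.000158, but adjusted p = 0.104 with an estimated correlation). Of 9156 genes tested, 2336 were called higher and 2561 lower, 4897 in all, of which 1228 and 140 by at least 2-fold. The genes named had adjusted p up to 5.74e-16 (edgeR, Benjamini-Hochberg).

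The Flag lines were also compared directly, WT minus E203Q (n = 2 libraries per group). At 1 to 1.5 h LanA stood at 30.1 CPM with Flag IntS11 WT and 856 with E203Q, Atg18b at 20.2 and 356, and Ect3 at 2.81 and 104. The log2 differences were -4.83 ± 0.06, -4.14 ± 0.06 and -5.21 ± 0.10. The apoptosis gene skl and the detoxification gene GstD5 differed by -5.24 ± 0.23 and -3.59 ± 0.18, and link, dan, gbb and snRNA:U11 were higher with WT by 1.85 ± 0.06, 1.92 ± 0.11, 1.88 ± 0.16 and 1.52 ± 0.14. Heat shock genes were lower in 10 of 17 cases, 10 adjusted over the list alone, while 2 were higher, with a median of -0.99 (camera adjusted p = 3.16e-07). Genes of p53 and apoptosis were lower in 6 of 8 cases, 6 adjusted over the list alone, while 1 was higher, with a median of -1.87 (camera adjusted p = 5.37e-05). The comparison called 4180 of 9156 genes, 2403 higher and 1777 lower, and by at least 2-fold 130 and 1063. For the genes named, adjusted p reached 7.93e-06 (edgeR, Benjamini-Hochberg). The share higher was 57.5%, or 32.6% with total counts and 64.9% with RLE size factors.

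In the same comparison at 2.5 to 3 h (n = 2 libraries per group), nub, byn, ths and Arc1 were higher with Flag IntS11 WT by 4.22 ± 0.12, 3.83 ± 0.09, 3.70 ± 0.16 and 3.67 ± 0.07. Transcripts of repo, CAH2, Atg18b and daw differed by -5.12 ± 0.15, -4.47 ± 0.08, -4.15 ± 0.06 and -3.60 ± 0.17, lower with WT. Early zygotic genes were higher in 31 of 39 cases, 31 adjusted over the list alone, while 5 were lower, with a median of 1.52 (camera adjusted p = 7.7e-20). Among maternal RNAs, those cleared at the transition were lower in 12 of 13 cases, 12 adjusted over the list alone, with a median of -1.37 (camera adjusted p = 4.16e-09). Calls numbered 6874 of 9156 genes, with 3454 higher and 3420 lower, 1570 and 1704 of them by at least 2-fold. The 50.2% higher became 41.9% with total counts and 54% with RLE size factors. The largest adjusted p of the genes named was 1.8e-15 (edgeR, Benjamini-Hochberg).

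**Figure D1:**
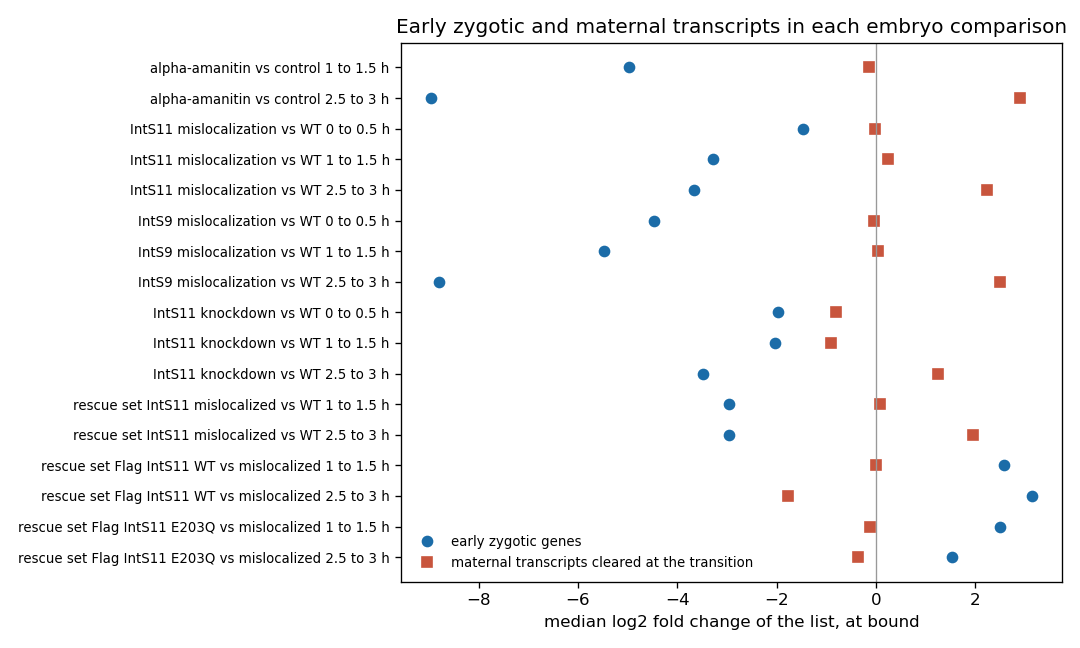
Median log2 fold change of the early zygotic genes (circles) and of maternal transcripts cleared at the transition (squares) in each embryo comparison, with genes of 3 or fewer counts in an arm at their bound. At 2.5 to 3 h the early zygotic median was negative in both mislocalization lines, the knockdown and alpha-amanitin, and positive for both Flag lines over the mislocalized line.

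Genes lowered at least 2-fold in the separate IntS11 mislocalization experiment were read as a group across the rescue lines. At 1 to 1.5 h these IntS11-lowered genes were lower in the mislocalized line (532 of 730 fell, median -2.05 or -1.68 at bound), and rose with Flag IntS11 WT (475 genes, median 1.90 or 1.58 at bound) and with E203Q (498 genes, median 1.98 or 1.62 at bound). The direct difference between the Flag lines in these genes had a median of 0.12 or 0.08 at bound (camera adjusted p = 0.213). Single genes still differed in both directions, 204 of 730 higher with WT and 165 lower, with quartiles of -0.61 and 0.73. Against wild type the group stood at -0.16 with Flag IntS11 WT and -0.32 with E203Q. At 2.5 to 3 h the IntS11-lowered genes had medians of -1.76 in the mislocalized line, 1.67 or 1.66 at bound for Flag IntS11 WT over it and 0.61 or 0.58 at bound for E203Q over it, where 1350 rose and 245 fell. Here Flag IntS11 WT exceeded E203Q in 2067 of 2689 of these genes and was below it in 139, median 1.16 (camera adjusted p = 8.04e-50). Against wild type the medians were 0.12 and -1.15.

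Genes changed at least 2-fold in both mislocalization lines at 0 to 0.5 h formed a group of 438 shared rises and one of 356 shared falls, against 54 and 36.5 for independent calls, and both groups were chosen after the data were seen. In the rescue experiment at 1 to 1.5 h the shared rises, among them LanA, Ect3, Atg18b, Hsp23 and mgl, were higher in the mislocalized line (median 2.28, 387 of 430 genes). Flag IntS11 WT lowered 304 of these genes (median -1.22), while with E203Q 170 rose further and 48 fell (median 0.31). The Flag lines differed in the shared rises by a median of -1.68, lower with WT in 361 of 430 genes (camera adjusted p = 4.01e-81). The shared falls, among them ftz, opa, twi and nkd, returned with either Flag line, by 2.48 with WT and 2.10 with E203Q, and the direct difference had a median of 0.47 (camera adjusted p = 1.19e-07). Against wild type at 1 to 1.5 h the shared rises stood at a median of 0.90 with Flag IntS11 WT, 177 higher and 5 lower, and 2.65 with E203Q, and the shared falls at -0.12 and -0.66. At 2.5 to 3 h these medians were 0.21 and 1.69 for the shared rises and 0.10 and -1.78 for the shared falls, where 321 of 356 were lower with E203Q. In the knockdown at 0 to 0.5 h 336 of 412 shared rises were higher (median 2.79, camera adjusted p = 6.47e-22). By 2.5 to 3 h 199 were higher in the knockdown and 118 lower, with a median of 0.765 (camera adjusted p = 0.026, but adjusted p = 0.223 with an estimated correlation). Under alpha-amanitin at 1 to 1.5 h the shared rises had a median of -0.07 (camera adjusted p = 0.591) and the shared falls one of -6.05 (camera adjusted p = 2.78e-60). Only 318 of the 438 shared rises were tested there. By 2.5 to 3 h 211 of these 318 were lower under alpha-amanitin and 62 higher (median -1.46, camera adjusted p = 0.000676). Medians of the shared groups are fitted values without bounds. The shared falls depend on zygotic RNA in wild type collections of 0 to 0.5 h, where the presence of older embryos was not tested. In that window an effect of the lines cannot be told apart from older embryos in wild type. LanA (dm6, 3L, 6203831 to 6218022), itself chosen after its values were seen, went from 45.6 to 454 CPM in the IntS11 line, from 13.1 to 1995 in the IntS9 line and from 73.04 to 2169 in the knockdown at 0 to 0.5 h.

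**Figure D2:**
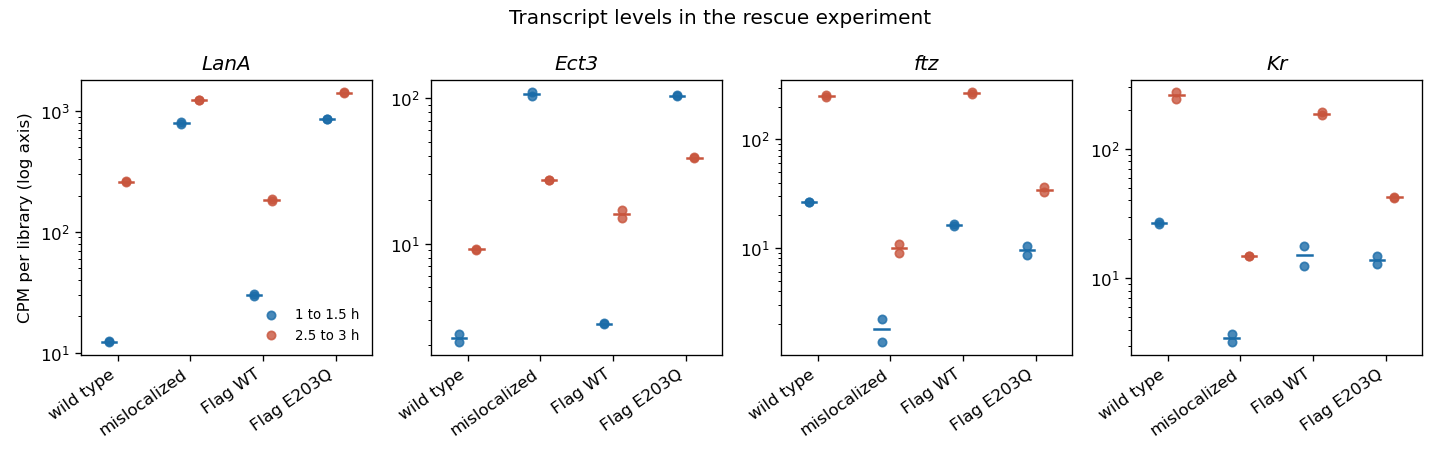
CPM of LanA, Ect3, ftz and Kr in each library of the rescue experiment on a log axis, at 1 to 1.5 h and 2.5 to 3 h. Points are libraries, n = 2 per group, and lines are their means. LanA at 1 to 1.5 h stood at 12.4 CPM in wild type, 794 in the mislocalized line, 30.1 with Flag WT and 856 with Flag E203Q.

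In zygotic mutant larvae at 24 h after egg laying (n = 2 libraries per group), Hsp68 went from 25.3 to 52.7 CPM (1.06 ± 0.08) and Hsp70Bb from 30.2 to 119.5 CPM (1.98 ± 0.10), though copies of Hsp70 share reads. The peroxiredoxin gene Prx2540-2, which has close copies as well, rose by 1.29 ± 0.15. The antifungal genes Drs and Drsl2 rose by 2.06 ± 0.19 and 2.47 ± 0.20, while IM3 and Mtk changed by -2.33 ± 0.25 and -2.31 ± 0.38. The lysozyme genes LysB and LysD went from 127 to 14.03 CPM and 185 to 0.629 CPM. Eggshell genes Cp15 and Cp38 changed by -1.61 ± 0.07 and -1.01 ± 0.09, and maternal osk by -0.42 ± 0.07. Eggshell and follicle cell markers fell in 7 of 17 cases, 8 adjusted over the list alone, while 2 rose, 6 over the list alone. The median was -0.16, or -0.09 without mutant replicate 1 (camera adjusted p = 1.15e-07, but adjusted p = 0.269 with an estimated correlation). Heat shock genes rose in 8 of 17 cases, 10 adjusted over the list alone, while 2 fell, with a median of 0.45 (camera adjusted p = 2.03e-17). Neuron markers rose in 9 of 10 cases, 9 adjusted over the list alone, with a median of 0.45 (camera adjusted p = 2.53e-10, but adjusted p = 0.269 with an estimated correlation). Among 11409 genes, 633 were called higher and 504 lower (1137 together), including 60 and 107 changed at least 2-fold. Each gene named had an adjusted p of 0.000489 or less (edgeR, Benjamini-Hochberg).

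At 48 h, fat body and eggshell transcripts were higher in zygotic mutants than in wild type (n = 2 libraries per group). The cuticle gene Lcp9 stood at 36.5 CPM in mutants, at least 430-fold higher. Yp1, Yp2, Lsp1gamma and Hsp70Bc rose by 6.23 ± 0.20, 5.55 ± 0.17, 7.45 ± 0.19 and 1.60 ± 0.28. LysB, LysE and Cyp6a8 changed by -4.59 ± 0.16, -3.40 ± 0.14 and -2.85 ± 0.14, and Jon99Fi, Jon66Cii and betaTry by -1.49 ± 0.07, -1.30 ± 0.07 and -1.08 ± 0.07. Among small nuclear RNAs, snRNA:U11 went from 63.5 to 13.8 CPM (-2.20 ± 0.27). Fat body markers rose in 6 of 6 cases, 6 adjusted over the list alone, and their sum went from 4819 to 8019 CPM. Over this list the median was 6.46 or 3.86 at bound (camera adjusted p = 4.13e-13). Digestive enzymes fell in 20 of 26 cases, 20 adjusted over the list alone, with a median of -0.51 (camera adjusted p = 9.46e-19, but adjusted p = 0.244 with an estimated correlation). Nucleolar and Cajal body RNAs (snoRNAs and scaRNAs) fell in 15 of 26 cases, 17 adjusted over the list alone, with a median of -1.54 or -1.17 at bound (camera adjusted p = 1.85e-10, but adjusted p = 0.26 with an estimated correlation). Eggshell and follicle cell markers rose in 17 of 17 cases, 17 adjusted over the list alone, and their sum went from 25.2 to 894 CPM. Their median log2 change was 5.03 (camera adjusted p = 3.48e-87). Maternal osk and gnu rose by 1.89 ± 0.10 and 2.17 ± 0.20. Whether these eggshell and maternal transcripts came from the larvae or from other material was not tested. Cuticle protein markers rose in 68 of 105 cases, 76 adjusted over the list alone, while 11 fell, 13 over the list alone, with a median of 1.74 or 1.69 at bound (camera adjusted p = 9.17e-15, but adjusted p = 0.293 with an estimated correlation). One mutant library stood apart in these genes, as their sum without Cpr was 27820 and 19060 CPM in the mutant replicates, and without mutant replicate 1 the median was 0.56. Of 11409 genes tested, 1826 were called higher and 1570 lower, 3396 in all, of which 694 and 122 by at least 2-fold. The genes named had adjusted p up to 0.00112 (edgeR, Benjamini-Hochberg).

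By 72 h stress and immune transcripts were higher in zygotic mutants (n = 2 libraries per group). The immune effector gene IM10 and the stress gene Victoria had 0 counts in wild type and 43.8 and 31.6 CPM in mutants, at least 579 and 417-fold higher. AttA, AttB, PGRP-SD, Drs, Ilp8 and Hsp70Bc rose by 5.24 ± 0.25, 4.65 ± 0.10, 5.22 ± 0.18, 6.62 ± 0.13, 4.99 ± 0.23 and 3.19 ± 0.23. The Osiris genes Osi6, Osi18 and Osi19 went from 669 to 2.80 CPM, 66.98 to 0.381 CPM and 61.2 to 0.588 CPM. LysB, nyo and Cpr65Eb changed by -6.53 ± 0.16, -6.39 ± 0.19 and -6.54 ± 0.33, and snRNA:U11 by -2.55 ± 0.19. Immune effectors rose in 15 of 15 cases, 15 adjusted over the list alone, and their sum went from 45.6 to 509 CPM. The median of this group was 3.19 (camera adjusted p = 9.1e-20). Heat shock genes rose in 16 of 17 cases, 16 adjusted over the list alone, with a median of 1.07 (camera adjusted p = 1.26e-05, but adjusted p = 0.285 with an estimated correlation). Fat body markers rose in 5 of 6 cases, 5 adjusted over the list alone, and their sum went from 4437 to 7883 CPM. As a group they had a median of 3.76 (camera adjusted p = 1.76e-16). Nucleolar RNAs fell in 26 of 26 cases, 26 adjusted over the list alone, with a median of -1.60 (camera adjusted p = 4.76e-05, but adjusted p = 0.641 with an estimated correlation). Digestive enzymes fell in 19 of 26 cases, 19 adjusted over the list alone, while 5 rose, and their sum went from 44450 to 24610 CPM. Over this list the median was -0.80 (camera adjusted p = 4.92e-06, but adjusted p = 0.641 with an estimated correlation). The comparison called 6529 of 11409 genes, 3034 higher and 3495 lower, and by at least 2-fold 823 and 799. For the genes named, adjusted p reached 2.37e-05 (edgeR, Benjamini-Hochberg).

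The calls of separate experiments at 2.5 to 3 h shared many genes. For the IntS11 and IntS9 lines, 2433 genes were higher in both and 3579 lower in both, 1.96 times the number for independent calls, with 288 opposite. For the IntS11 line and its repeat in the rescue experiment, 2436 genes were higher in both and 3227 lower in both, 1.93 times the number for independent calls, with 472 opposite. For the IntS11 line and the knockdown, 1661 genes were higher in both and 2104 lower in both, 1.46 times the number for independent calls, with 1591 opposite, and for the IntS11 line and alpha-amanitin, 1707 genes were higher in both and 2816 lower in both, 1.43 times the number for independent calls, with 1712 opposite. In one-sided Fisher's exact tests the largest p of these shared rises and shared falls was 1.29e-171. These tests treat genes as independent, though many change together, and do not measure the spread between samples.

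Some transcripts, chosen after their values were seen, were near 0 CPM in some fly lines and not in others. The eye color gene w stood at 0.846 CPM in wild type and 1612 in the IntS11 line at 0 to 0.5 h, 1298 in the IntS9 line, 188 in the knockdown and 3034 and 2233 in the Flag lines at 1 to 1.5 h. Cyp12c1, at 21.3 CPM in rescue wild type at 1 to 1.5 h, was at 0.0938 in the mislocalized line and at most 0.132 in the Flag lines. Cyp12d1-d stood at 4.75, 0, 24.9 and 0 CPM in the same order, and Dh44-R2 at 83.9, 0.153, 17.5 and 33.6, so the Flag lines differed from each other in such markers. The summed copies of His1 went from 38.7 to 3.41 CPM in the IntS11 line and from 41.1 to 0 in the IntS9 line at 0 to 0.5 h, where copies share reads, while the single-copy variant gene His2Av went from 315 to 328 and from 429.5 to 365.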

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

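The tests of differences between effects were planned, and the tests of the patterns were chosen after the results were seen. The effects of IntS11 and IntS9 mislocalization differed in 3527 of 9459 genes at 1 to 1.5 h, higher with IntS11 in 1693 and lower in 1834, of which 500 and 395 by at least 2-fold. At 2.5 to 3 h their effects differed in 3088 genes, 1636 and 1452 by direction. The effects of IntS11 mislocalization and knockdown at 2.5 to 3 h differed in 6353 of 10517 genes, 3286 and 3067 by direction. The balance of direction turned with RLE size factors in all of these, as the share higher went from 48% to 55.4%, from 53% to 49.6% and from 51.7% to 42.6%. Each joins experiments with wild type libraries of their own, so a difference between experiments cannot be separated from one between perturbations.

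Transcripts higher in both mislocalization lines at 0 to 0.5 h were 438 genes, with LanA, Ect3 and Hsp23 among them, and 430 were tested in the rescue experiment. At 1 to 1.5 h 304 of these were lower with Flag IntS11 WT than in the mislocalized line and 7 were higher, with a median of -1.22. RNA of follicle cells that make eggshell would bring eggshell transcripts. Their sum was at most 0.0272% of the summed gain of the list, which argues against such cells. In the IntS9 line this sum was at most 4.57 CPM, with 0.456 in wild type, against a gain of 16790 CPM. Follicle cells without eggshell transcripts were not tested. The list was lower with Flag IntS11 WT than with E203Q by a median of -1.68, which a dependence on the changed residue would need, as a hypothesis found and tested on the same data. Alleles of the listed genes on some chromosome arms alone would leave other arms without the fall, but the arm with the weakest median still fell by 1.07 and that with the strongest by 1.35, which argues against them. The list was also higher in the separate knockdown at 0 to 0.5 h, in 336 of 412 genes. Alleles would explain this only if that line shared them. Alleles on every arm, shared by these lines, cannot be told apart from the residue. Outside the list, 13 genes differed at least 4-fold between the Flag IntS11 WT and mislocalized lines in both windows without a call in the separate IntS11 experiment, and they lay on 5 of 5 arms, so no arm can serve as a reference. The Flag lines also differed from each other in transcripts such as Cyp12d1-d.

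Summed His1 copies were lower with mislocalized or depleted IntS11 or IntS9, and even the weakest log2 change over the 4 earliest comparisons was -3.51, which argues against reads moved among the counted copies. Under alpha-amanitin at 1 to 1.5 h the sum changed by 1.07, which argues against absent zygotic transcription. Of 23 His1 copies 8 had 0 counts in all libraries, and 13 equalled another copy in every library, as with reads divided among copies. The His2A, His3 and His4 repeat copies held at most 1.1 CPM in sum in any group, and the reason was not tested. Lower His1 RNA therefore cannot be told apart from counts of some copies alone, whose variants differ between the lines. In the rescue experiment at 1 to 1.5 h the His1 sum was 42.3 CPM in wild type, 1.54 in the mislocalized line, 29.5 with Flag IntS11 WT and 6.14 with E203Q.

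Larval fat body transcripts such as Lsp2 and Fbp1 stood out in knockdown embryos at 0 to 0.5 h, where libraries were deeper and held a larger share of 7SL RNA. After thinning to equal depth without 7SL RNA the median fat body marker was still 8.37 log2 units higher, a fitted value over 0 counts for which 6.37 at bound was the floor before thinning, which argues against depth as the whole cause. Larvae at the ages of this series held less Lsp2, Fbp1 and Fbp2 than these embryos, 3 of the 7 markers. For each gene in that order, the highest larval library held 4.90, 0.221 and 0.168 CPM. The lower knockdown library held 314, 130.5 and 13.5 CPM, and Lsp2 differed by at least 64.1-fold in every pair of libraries. Larval values of Fbp1 and Fbp2 lay below the floor of 0.304 CPM of the 48 h mutants, so no fold is given for them. The levels of these 3 markers argue against such larvae as the whole source, while the other 4 markers stood below their highest larval level. RNA of older larvae cannot be told apart from other sources, since no larval group held more than 4.82 CPM of Lsp2 and none can serve as a reference. Gut digestive enzymes rose as well at 0 to 0.5 h, in 20 of 25 cases, with a median of 3.39, 2.29 at bound or 5.52 without wild type replicate 1 (camera adjusted p = 0.0214, but adjusted p = 0.568 with an estimated correlation). At 1 to 1.5 h they rose in 25 of 25 cases, and cuticle genes Lcp4 and Lcp65Ab1 appeared from 0 counts. Muscle markers went the other way at 0 to 0.5 h, lower in 7 of 12 cases and higher in 2. Wild type libraries of the IntS9 experiment at 0 to 0.5 h also held Lsp2, at 12.6 CPM. RNA from larval tissues of several kinds, or expression in the embryos, stays open, and no biological explanation was tested.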

How the results depend on the processing

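Most settings were fixed before the data were examined, and thinning of the knockdown libraries and the medians of gene lists with a library left out were chosen after seeing the data. Over 25 counts of called genes, 252 of 265 alternatives stayed within 1.5 times the main count and 13 did not. No reported gene, list or overlap reversed its direction. A count of calls has no direction, and the balance of higher and lower calls did turn with the scaling in some comparisons. With only the groups compared, Flag IntS11 WT against the mislocalized line at 1 to 1.5 h gave 1136 genes in place of 2213, and against E203Q 2380 in place of 4180, as fewer samples informed the spread. DESeq2 gave 2360 genes in place of 4000 for E203Q against the mislocalized line at 1 to 1.5 h and 668 in place of 1137 for larvae at 24 h, and the cause was not tested.

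Leaving out each library in turn, where the lone sample was assumed to vary like the other groups, gave 1758 to 2924 genes for IntS11 mislocalization at 0 to 0.5 h (main count 2790), the fewest without wild type replicate 2, and 1787 without mutant replicate 2. The range was 1499 to 2184 for alpha-amanitin at 1 to 1.5 h (main 2851), with 1499 and 1510 without treated replicates 1 and 2 and 1662 without control replicate 2. For larvae at 24 h it was 490 to 852 (main 1137), with 490 and 733 without mutant replicates 1 and 2 and 607 without wild type replicate 1. For the difference of the IntS11 and IntS9 effects at 1 to 1.5 h it was 2179 to 3652 (main 3527), the fewest without IntS11 wild type replicate 1. These fits had fewer samples. Of 66 gene lists reported, 3 had a median that moved over 1.5 times without a library: cuticle markers at 48 h (0.558 in place of 1.74) and eggshell markers at 24 h (-0.086 in place of -0.161), both without mutant replicate 1, and gut enzymes in the knockdown at 0 to 0.5 h (5.52 in place of 3.39, without wild type replicate 1).

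Of 142 alternatives for lists read in another experiment, 140 kept their side of the threshold. With an estimated correlation the amanitin-lowered genes in the knockdown at 1 to 1.5 h kept their median of -1.10 but had adjusted p = 0.0983 (camera, range over the alternatives 4.81e-08 to 0.0983). With total counts the IntS11-lowered genes in Flag IntS11 WT against E203Q at 1 to 1.5 h had a median of 0.015 and adjusted p = 0.00768 (camera, range over the alternatives 0.00768 to 0.484), and the cause was not tested. Of 932 pairs of list and comparison, 368 passed with the preset correlation and 143 with an estimated one, and the cause of the drop was not tested. All 16 alternatives of the overlaps kept their direction and side.

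Correlations of replicate deviations had medians from -0.173 to 0.084 within experiments but reached 0.65 for one pair of groups, 0.449 for IntS11 mislocalization at 2.5 to 3 h and 0.421 for Flag IntS11 WT against the mislocalized line at 1 to 1.5 h. Replicate numbers were not used as pairs, and with a replicate block the latter comparisons gave 7428 genes in place of 7331 and 2300 in place of 2213, and IntS11 mislocalization at 0 to 0.5 h 3163 in place of 2790. Thinned to equal depth without 7SL RNA, the knockdown gave 5864, 6043 and 6257 genes in the windows from first to last, in place of 6690, 7041 and 7331. Depth limits the wild type libraries of that experiment most, where a transcript at 0 counts was not detectable rather than absent.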

Other observations

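The return of IntS11-lowered genes with Flag IntS11 E203Q was partial at 2.5 to 3 h, and both tests of it were chosen after it was seen. A need of longer genes for the residue was tested over 2673 lowered genes, where gene span and the E203Q change from wild type had a Spearman coefficient of -0.057, which argues against it. Slower development could also lower these genes, and the change of wild type embryos with age in another experiment had a coefficient of -0.49 with the E203Q change over 8598 genes. The coefficient was 0.04 for Flag IntS11 WT, -0.63 for the mislocalized line and -0.89 for alpha-amanitin. Slower development and less transcription of zygotic genes cannot be told apart here, since both lower the genes that rise with age, and genes are not independent replicates.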
